A study of Mus musculus with 20 samples.

How the data were processed

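Expression was measured in 20 libraries from mouse preimplantation embryos of wild-type genotype, prepared with the Smart-seq2 protocol per the labels. The libraries form 10 groups of 2, which are control and P300 siRNA at 4 stages (late 2-cell, 4-cell, early 8-cell and late 8-cell) and P300 siRNA with I1394G or with NaCr at the late 8-cell stage. The series design text names fewer stages than the samples hold, and all 4 stages of the samples were used.

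The count table holds raw counts per gene, deposited by the authors without normalisation. The FPKM table holds fragments per kilobase of transcript and mapped fragments, deposited by the authors. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 4.1, HISAT2 2.2.1, Cufflinks 2.2 and the genome build mm9, without stating the settings of each. Counting was not stated to use strand, so reads of overlapping and antisense genes could not be separated. Both tables list 25208 genes by symbol, and every column was matched to its sample through the sample descriptions. For 19 libraries the log2 count and FPKM columns correlated at 0.997 or above over 7134 genes with a mean count over 200. For control early 8-cell replicate 2 the correlation was 0.899. Counts were therefore used for every comparison, and FPKM only as an alternative. The 2 libraries of a group were checked not to be copies of each other, and the correlation of their log2 CPM lay between 0.964 and 0.994.

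Total counts per library ranged from 3.20 M to 24.8 M. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the default low-count filter applied to the groups, which left 16603 genes. Library sizes were scaled with TMM factors, and CPM values printed in the text were computed here from these scaled sizes. A negative binomial model with 1 coefficient per group was fitted to all 20 libraries, with 10 residual and 7.98 prior degrees of freedom. Contrasts were tested with the two-sided quasi-likelihood F test and p values were adjusted by the Benjamini-Hochberg method, with a call at an adjusted p under 0.05. The SE of a log2 fold change was taken as its size over the square root of F. The contrasts were P300 siRNA against control at each stage and averaged over the 4 stages, a joint test and a late against early 8-cell test of differences between stages, each treated group against siRNA, against control and against the other, and successive stages within the controls.

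The fitted test was tested on simulated data with 16091 genes at the real depths. Of genes changed 4-fold it recovered 72.5%, 86.2%, 75.4% and 81.2% at the late 2-cell, 4-cell, early 8-cell and late 8-cell stages. For 2-fold changes it recovered 12%, 16.4%, 18.9% and 20%, and for 1.5-fold changes 1.79%, 1.47%, 2.44% and 1.52%, with 2, 1, 2 and 3 false calls. A gene without a call is therefore not an unchanged gene.

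There were 31 gene lists written from general knowledge of early embryos. They cover histone acylation, embryonic lineages, polarity, Hippo signalling, stress responses, ribosomes, mitochondria, metabolism, cell division, chromatin, maternal and 2-cell transcripts, and markers of other cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists within a comparison. They were tested again with the correlation estimated for each list. Across 10 comparisons 87 list calls passed with the preset value and 12 with the estimated value. Genes were named by a rule: Ep300 in every library, then up to 10 largest rises and 10 largest falls per comparison. These had to pass the test, to hold at least 10 CPM in the higher group and to keep both libraries of a group above both of the other, and unnamed gene models were left out. Members of the lists followed in order of adjusted p, and for a list without a call the most abundant member. Nanog and Cdx2, which the rule named in 1 comparison each, were followed in the others, as was Wdfy1 at later stages after its values were seen. The comparisons, tests, lists, naming rule and main alternatives were fixed before the data were examined.

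The genes called at the early 8-cell stage were tested with camera in the treated groups. For late 8-cell calls, which share the siRNA libraries with the treated comparisons, 20 simulated draws with treated groups equal to the siRNA group gave the value without any reversal, and 20 more gave it without any effect of the siRNA. Genes changing with stage were taken at an absolute log2 fold change of at least 1 from control libraries outside the tested comparison. Replicate numbers did not pair the libraries and no block was used.

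Alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, limma on log2 FPKM with a pseudocount of 1 (at least 1 FPKM in 2 libraries), a minimum log2 fold change of 1, only the libraries of the groups compared, a replicate block, estimated correlations and leaving out each library in turn. In the last of these a group may hold 1 library, which is assumed to vary like the other groups. A fit without the late 2-cell libraries and an FPKM fit without the unmatched column were added after the data were seen. The reference annotation (assembly GRCm38) differs from the build of the files and was used only to place genes on chromosomes by symbol, which matched 16583 of 16603 tested genes. Reads were not analysed here.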

Results

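RNA sequencing measured gene expression in mouse preimplantation embryos cultured from the zygote and labelled control or P300 siRNA. The 20 libraries form 10 groups of 2. Control and P300 siRNA embryos were taken at the late 2-cell, 4-cell, early 8-cell and late 8-cell stages, and the late 8-cell stage holds 2 further groups, P300 siRNA with I1394G and P300 siRNA with NaCr. The labels do not spell out I1394G and NaCr. They were read here as a point mutant of p300, the acetyltransferase encoded by Ep300, and as sodium crotonate, which feeds histone crotonylation. The counts deposited for a library summed to between 3.20 M (M, mega; P300 siRNA, late 8-cell, replicate 1) and 24.8 M (I1394G, replicate 2). Across the other libraries, the totals were 11.5 and 8.10 M for late 2-cell controls, 5.37 and 9.51 M for late 2-cell siRNA, 11.2 and 23.5 M for 4-cell controls, and 7.17 and 15.8 M for 4-cell siRNA. At the early 8-cell stage they were 11.7 and 12.9 M for controls and 10.99 and 8.20 M for siRNA. At the late 8-cell stage they were 22.7 and 21.2 M for controls, 20.3 M for siRNA replicate 2, 21.2 M for I1394G replicate 1, and 17.5 and 9.29 M for NaCr. Group levels are CPM, counts scaled to the library size, as mean ± SD with n = 2 libraries, changes are log2 fold changes ± SE, and adjusted p values are those of edgeR's two-sided quasi-likelihood test unless another test is named. Folds against a group without counts are lower bounds set at 3 counts over the group, and these bounds cover counting error only.

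Ep300 encodes the siRNA's target and was lower in P300 siRNA embryos at the 4-cell and early 8-cell stages. At the late 2-cell stage it read 86.1 and 83.8 CPM in the controls and 22.6 and 29.9 CPM in the siRNA libraries, a change of -1.69 ± 0.37 that did not pass over all genes (adjusted p = 0.318). At the 4-cell stage the controls held 48.3 and 88.4 CPM and the siRNA libraries 11.4 and 19.1 CPM (-2.15 ± 0.37, adjusted p = 0.00128). At the early 8-cell stage they held 41.5 and 82.9 CPM against 11.7 and 16.4 CPM (-2.15 ± 0.37, adjusted p = 0.000819). At the late 8-cell stage Ep300 did not part the groups, with 22.0 and 15.2 CPM in the controls and 16.2 and 13.2 CPM in the libraries labelled P300 siRNA (-0.36 ± 0.37, adjusted p = 0.4997). The I1394G group held 15.5 ± 1.06 CPM and the NaCr group 12.1 ± 0.712 CPM, neither of which differed from the siRNA group (adjusted p = 0.913 and 0.665) or from the controls (adjusted p = 0.778 and 0.490). In the controls themselves, Ep300 fell by 1.74 on the log2 scale between the early and late 8-cell stages (SE 0.36, adjusted p = 0.00205). Averaged over the 4 stages, Ep300 was lower by -1.59 ± 0.18 (adjusted p = 5.5e-06). Ep300 therefore checks neither the siRNA label nor the I1394G label at the late 8-cell stage, and directions given there rest on the labels.

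**Figure D1:**
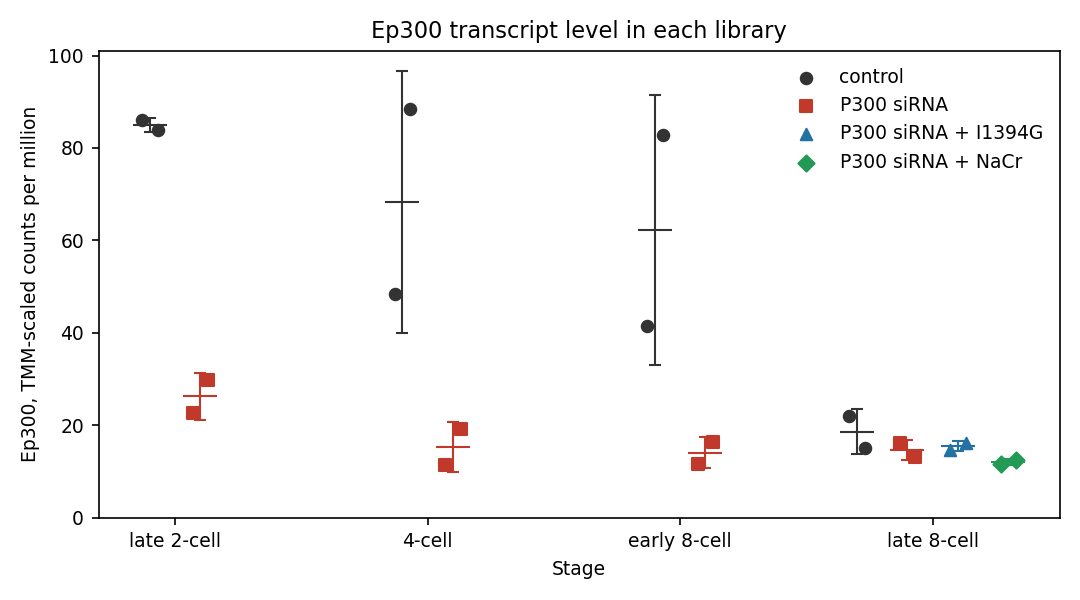
Ep300 level in CPM (vertical axis) in each of the 20 libraries, by stage and group. Points are libraries, the horizontal line is the mean and bars show the SD (n = 2); the siRNA libraries lie at 11.4 to 29.9 CPM, and the late 8-cell controls at 22.0 and 15.2 CPM.

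At the late 2-cell stage, just after the main wave of embryonic genome activation, 1 gene passed. Wdfy1, an endosomal adaptor in innate immune signalling, rose by 2.34 ± 0.31, from 8.58 ± 2.78 to 43.4 ± 17.0 CPM (adjusted p = 0.00779). At the 3 later stages Wdfy1 was lower in siRNA embryos instead, by 1.17, 1.24 and 1.60 (adjusted p = 0.0112, 0.00627 and 0.000639). Of the fixed gene lists, maternal oocyte transcripts were lower as a set (median -0.26, camera adjusted p = 0.000798, adjusted p = 0.657 with an estimated correlation), and none of the 41 members passed. Tcl1, an AKT co-activator stored in the oocyte and the most abundant member, stood at -0.24 ± 0.46 (adjusted p = 1). Ribosomal protein genes (81 tested), ribosome biogenesis genes (73) and p53 targets (26) were higher as sets, with medians of 0.23, 0.19 and 0.25, again without a member that passed. Their camera adjusted p values were 2.7e-09, 3.9e-07 and 0.000866, against 0.873, 0.664 and 0.535 with an estimated correlation. Adjusted over the list alone, 1 ribosomal protein gene and 1 p53 target rose. Their most abundant members were Rplp0 (0.19 ± 0.16), Npm1 (0.13 ± 0.15) and Ei24 (0.19 ± 0.33), all with adjusted p = 1. Nanog (-0.89 ± 0.78) and Cdx2 (0.15 ± 1.36) did not pass either (adjusted p = 1 for both). At an unadjusted p under 0.05 edgeR held 689 genes, fewer than by chance, so 1 call need not mean little effect. DESeq2 called 33, unfiltered edgeR 12, limma on FPKM 79 and a fit of these 4 libraries alone 508. Wdfy1 lost its call without replicate 1 of either group. The ribosome biogenesis call was lost without siRNA replicate 2 (adjusted p = 0.393).

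At the 4-cell stage, P300 siRNA embryos held more transcripts of glycolytic enzymes and fewer transcripts of the pluripotency network. In all, 2494 of 16603 genes changed, 1290 higher and 1204 lower. Glycolytic Ldha, which makes lactate, rose by 3.73 ± 0.32, from 24.4 ± 3.30 to 322 ± 55.4 CPM (adjusted p = 4.1e-06). Among the largest rises, Stat6, a cytokine-activated transcription factor, was at least 156-fold higher (14.8 ± 2.64 CPM), and the X-linked homeobox gene Rhox6 was at least 123-fold higher (11.7 ± 1.53 CPM), both with no counts in controls. The MAGE family gene Magea10 rose by 8.07 ± 0.86, Ct55, a cancer-testis antigen, by 6.86 ± 0.90, and Bex2, a small brain-expressed X-linked gene, by 6.21 ± 0.80. Gchfr (6.43), Rhox9 (6.08) and Klhl13 (5.79) also rose, while Pramel3 (30.2 against 0.155 CPM) and Rhox2a (18.5 against 0.103 CPM) rose from 3 and 2 control counts. The largest falls were those of Ly6a, a GPI-anchored surface protein, at -5.80 ± 0.65, and of the calmodulin-like Calm5 at -5.77. Dusp6, a phosphatase that ERK signalling induces, fell by 4.97 (SE 1.02), a change of -1.62 without control replicate 1 (adjusted p = 0.103). Acadl, which starts long-chain fatty acid oxidation, fell by 3.66 (SE 0.34), to 12.8 ± 2.46 from 161 ± 69.3 CPM (adjusted p = 8.5e-06). Dynap, Tspan1, Cnmd, Plcd1 and Gprc5a fell by between 3.83 and 4.23, with Cnmd at -2.33 without control replicate 1. Members of the Rhox, Mage, Prame and Ly6 families resemble one another, so reads could be split between copies in the deposited counts and their values are uncertain.

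Among the lists at the 4-cell stage, 11 of 21 glycolysis genes rose and none fell (12 rose adjusted over the list alone), with Eno1 at 2.42 ± 0.26 and Gpi1 at 2.06 ± 0.24 beside Ldha. The list's median was 1.43 (camera adjusted p = 6.4e-09, and 0.0295 with an estimated correlation). Of 30 inner cell mass and pluripotency genes, 13 fell and 1 rose (18 and 2 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 2.6e-08, and 0.0468 with an estimated correlation). They included the nuclear receptor Nr5a2 at -1.74 ± 0.22 (71.5 ± 10.1 against 238 ± 8.75 CPM) and Klf5 at -1.61 ± 0.23, a factor of both early lineages, while Nanog (0.17 ± 0.49, adjusted p = 0.879) and the trophectoderm gene Cdx2 (0.07 ± 1.71, adjusted p = 1) did not pass. Hippo pathway genes fell, 6 of 20 against 2 that rose (9 and 2 adjusted over the list alone), among them the effectors Tead4 at -1.73 ± 0.28 and Wwtr1 at -1.28 ± 0.24 (median -0.79, camera adjusted p = 0.00826, adjusted p = 0.0987 with an estimated correlation). Stk3, a kinase that restrains those effectors, rose (1.26 ± 0.30). Of 73 ribosome biogenesis genes, 20 fell and none rose (26 adjusted over the list alone), including Polr1b, of RNA polymerase I, at -1.31 ± 0.21 (median -0.44, camera adjusted p = 3.1e-09, adjusted p = 0.448 with an estimated correlation). Histone methylation genes (6 of 32 fell, Kdm5b at -1.25 ± 0.20), DNA replication genes (6 of 41 fell and 2 rose, Cdc6 at -1.76 ± 0.24) and mitosis genes (8 of 28 fell and 1 rose, Kif23 at -1.05 ± 0.21) had camera adjusted p = 0.0129, 0.0327 and 0.00904, against 0.456, 0.448 and 0.582 with an estimated correlation. Adjusted over the list alone, 8, 7 and 9 of them fell and 3, 3 and 2 rose. Of 26 p53 targets, 6 rose and 1 fell, the same counts adjusted over the list alone, with the pro-apoptotic Pmaip1 at 2.92 ± 0.34 and the antiproliferative Btg2 at 2.96 ± 0.36. The p53 median was 0.27, or 0.29 with genes without counts at their bound, with camera adjusted p = 0.0183 and adjusted p = 0.448 with an estimated correlation. Respiratory chain genes (9 of 86 rose, Uqcrfs1 at 0.68 ± 0.18 among the smaller rises), mitochondrial ribosomal protein genes (5 of 75 rose, Mrps35 at 1.17 ± 0.22) and proteasome genes (4 of 39 rose and 1 fell, Psmd10 at 1.49 ± 0.26) had camera adjusted p = 3.6e-05, 0.0253 and 0.0183, each 0.668 with an estimated correlation. Adjusted over the list alone, 4, 3 and 4 of these rose and 0, 0 and 1 fell. Xist, which silences an X chromosome in female embryos, differed between the controls, at 72.8 CPM in replicate 1 and 0.367 CPM in replicate 2, and read 87.3 and 73.4 CPM in the siRNA libraries. The number of genes called fell to 1383 without control replicate 2 and to 1562 without siRNA replicate 1, was 1368 with limma on FPKM, and was 59 when these 4 libraries were fitted alone. Of the 38 genes named and called here, Dusp6, Kif23, Stk3, Uqcrfs1 and Wdfy1 lost the call without 1 of the libraries. Without control replicate 2 the lists of p53 targets, respiratory chain, mitochondrial ribosomal proteins, proteasome, mitosis, DNA replication and histone methylation were no longer called (adjusted p = 0.057, 0.0758, 0.653, 0.495, 0.305, 0.0758 and 0.0824). Without siRNA replicate 1 the same held for mitochondrial ribosomal proteins, proteasome, mitosis, DNA replication and histone methylation (0.0747, 0.0521, 0.106, 0.202 and 0.0747), and without siRNA replicate 2 for p53 targets (0.138).

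The early 8-cell stage, when embryos are about to compact, held 2741 changed genes, 1363 higher and 1378 lower in P300 siRNA embryos. The glycolytic enzymes rose again and pluripotency factors fell. Rarb, a retinoic acid receptor, was at least 71.1-fold lower, from 10.5 ± 8.19 CPM to no counts. Dusp6 fell by 7.88 (SE 1.10), the growth factor genes Bmp4 by 5.36 (SE 1.48) and Nrg1 by 4.82 (SE 0.79), and Hopx, an atypical homeodomain gene, by 5.32 (SE 1.23). The integrin subunit gene Itga3 fell from 26.1 to 0.0435 CPM, a single count, and Calm5, Tspan1, Slc30a2 and Ly6a fell by 5.82, 4.82, 4.52 and 4.41. On the other side, Poglut2, a glycosyltransferase, was at least 73.0-fold higher (10.3 ± 7.24 CPM), and Klhl13, an X-linked ubiquitin ligase adaptor, rose by 6.77 ± 0.90. Zfp280c rose by 5.85 ± 0.77, from 1.11 to 63.6 ± 11.5 CPM, and Gstm1 (5.76), Rhox2a (6.05), Bex2 (5.57) and Magea10 (5.55) rose too. Sohlh2 (18.0 against 0.0492 CPM), Slc7a3 (21.8 against 0.0984 CPM) and Pla2g1b (12.9 against 0.148 CPM) rose from 1 to 3 control counts.

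At this stage 17 of 30 pluripotency genes fell and 1 rose (19 and 1 adjusted over the list alone), led by Klf5 at -2.20 ± 0.24 (25.5 ± 3.01 against 117 ± 18.3 CPM), Tbx3 at -4.16 ± 0.50 and Nr5a2 at -1.72 ± 0.22. Their median was -1.05, or -1.10 with genes without counts at their bound (camera adjusted p = 7.0e-11, and 0.0202 with an estimated correlation). Nanog did not pass (-0.26 ± 0.49, adjusted p = 0.776). Trophectoderm genes fell, 10 of 29 against 2 that rose (10 and 3 adjusted over the list alone), with Tfap2c at -1.77 ± 0.23 and Tead4 at -2.16 ± 0.28. The X-linked homeobox gene Esx1, of the placenta, rose by 3.93 ± 0.55. Cdx2 was at least 12.1-fold lower, from 1.79 ± 0.2503 CPM to no counts (adjusted p = 0.0150, and 0.0901 and 0.0666 without siRNA replicates 1 and 2). The trophectoderm median was -1.16, or -1.20 at the bounds (camera adjusted p = 0.000161, adjusted p = 0.268 with an estimated correlation). Hippo pathway genes fell, 8 of 20 against 1 that rose, the same counts adjusted over the list alone, with Wwtr1 at -1.72 ± 0.25 and Vgll4 at -3.05 ± 0.54 (median -0.70, camera adjusted p = 8.7e-05, and 0.0254 with an estimated correlation). Glycolysis genes rose, 11 of 21 against 3 that fell (13 and 4 adjusted over the list alone), with Pkm at 2.98 ± 0.25, Ldha at 3.48 ± 0.31 and Eno1 at 2.76 ± 0.26 (median 1.71, camera adjusted p = 2.1e-06, and 0.036 with an estimated correlation). Of 26 p53 targets 7 rose and none fell (11 adjusted over the list alone), including Ccng1 at 2.84 ± 0.38 and Pmaip1 at 2.80 ± 0.34 (median 0.58, or 0.60 at the bounds, camera adjusted p = 0.000164, adjusted p = 0.121 with an estimated correlation). Of 73 ribosome biogenesis genes 15 fell and none rose (21 adjusted over the list alone), including Tsr1 at -1.29 (median -0.39, camera adjusted p = 2.1e-06, adjusted p = 0.678 with an estimated correlation). Ribosomal protein genes were lower as a set, with 3 of 81 members fallen and none adjusted over the list alone, Rpl10a at -0.56 (camera adjusted p = 0.00485, adjusted p = 0.917 with an estimated correlation). Respiratory chain genes were higher as a set, with 8 of 86 risen and 1 fallen (6 and 1 adjusted over the list alone), Sdhd at 1.41 and the lung isoform gene Cox4i2 at -2.76 (camera adjusted p = 0.0168, adjusted p = 0.917 with an estimated correlation). The number of genes called fell to 1313 without control replicate 2, 1654 without siRNA replicate 1 and 1729 without siRNA replicate 2. It was 165 with limma on FPKM, and 1661 when the FPKM column of control replicate 2, which did not match its count column, was left out. Of the 40 genes named and called, Bmp4, Hopx, Cox4i2, Rpl10a, Cdx2 and Wdfy1 lost the call without 1 of the libraries, and 36 with limma on FPKM.

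At the late 8-cell stage, when embryos compact and polarise, P300 siRNA embryos held less Cdx2. The sets of pluripotency factors and ribosome components were lower and those of p53 targets, glycolytic enzymes and maternal oocyte transcripts higher at the preset correlation, and 0 of the 31 lists passed with an estimated correlation (lowest adjusted p = 0.0945). Here 4645 genes changed, 2266 higher and 2379 lower. With DESeq2 size factors the median of all genes moved by 0.136 and the share of higher calls from 48.8% to 58.4%. Cdx2, the trophectoderm master gene, fell by 6.44 (SE 1.28), to 0.102 ± 0.144 from 14.8 ± 1.28 CPM (adjusted p = 0.00159). Enpep fell by 4.87 (SE 0.69), to 2.55 ± 0.144 from 73.8 ± 16.6 CPM, Siglecg by 5.87 (SE 1.28) and Bmyc by 4.85 (SE 0.74). Ly6f fell from 23.3 to 0.0204 CPM, a single count, and Calm5, Alox5ap, Serpinb6c, Saxo1 and Msc fell by between 4.78 and 6.36. Sncg was at least 519-fold higher (41.4 ± 18.8 CPM), and Zcchc12, Nap1l5 and Nrk were at least 219-fold, 163-fold and 149-fold higher, none of them with a count in controls. Mzb1 rose from 0.0808 to 31.2 ± 0.535 CPM, and Crabp1, Tmem59l, Akr1b10, Csf1 and Trf rose from 1 or 2 control counts. These libraries also held more genes overall. At an equal depth of 3200000 counts, 16348 ± 607 genes were detected in the siRNA group against 14468 ± 19.1 in controls, 15071 ± 67.9 with I1394G and 14628 ± 33.2 with NaCr. Of 1491 receptor genes silent in early embryos, 71 and 67 had a count at that depth in the siRNA libraries against 36 and 40 in controls.

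Of 81 ribosomal protein genes at the late 8-cell stage, 56 fell and 1 rose (67 and 1 adjusted over the list alone), with Rpl5 at -1.24 ± 0.17 (1159 ± 60.9 against 2733 ± 25.5 CPM) and Rpl3 at -1.25 ± 0.18. Their median was -0.87 (camera adjusted p = 9.2e-17, adjusted p = 0.308 with an estimated correlation). Of 73 ribosome biogenesis genes 40 fell and none rose (45 adjusted over the list alone), including Tbl3 at -1.70 ± 0.20 and Ddx56 at -1.28 ± 0.15 (median -0.70, camera adjusted p = 2.5e-14, adjusted p = 0.265 with an estimated correlation). Mitochondrial ribosomal protein genes fell, 31 of 75 against 0 (37 adjusted over the list alone), with Mrpl17 at -1.68 ± 0.22 (median -0.53, camera adjusted p = 9.3e-08, adjusted p = 0.308 with an estimated correlation). Proteasome genes (9 of 39 fell and 1 rose, also adjusted over the list alone, Psmd3 at -1.48 ± 0.19), DNA replication genes (15 of 41 fell and 2 rose, 16 and 2 adjusted over the list alone, Mcm3 at -1.64 ± 0.21) and heat shock genes (9 of 20 fell and 1 rose, 11 and 2 adjusted over the list alone) were lower as sets. Their medians were -0.37, -0.43 and -0.60, with camera adjusted p = 0.000329, 0.000233 and 0.0181, against 0.318, 0.132 and 0.308 with an estimated correlation. The heat shock gene that rose was Hspb1 (3.60 ± 0.28), whereas Stip1 fell by 1.24 (SE 0.16). Mitosis genes (8 of 28 fell and 1 rose, 10 and 2 adjusted over the list alone, Cdk1 at -0.98 ± 0.18 and Pttg1, the securin gene, at 1.31 ± 0.28) had camera adjusted p = 0.0265. It was 0.479 with an estimated correlation and 0.071 with DESeq2 size factors. Respiratory chain genes (17 of 86 fell and 3 rose, 15 and 3 adjusted over the list alone, Ndufs1 at -0.98 ± 0.23, with the testis isoform gene Cox6b2 at 3.73 ± 0.52) had a median of -0.33 and camera adjusted p = 0.0124, adjusted p = 0.653 with an estimated correlation. Without siRNA replicate 1 that median turned to 0.06, and without control replicate 2 the respiratory chain call was lost (adjusted p = 0.0508). The mitosis call was lost without siRNA replicate 2 (adjusted p = 0.0836).

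Of 30 pluripotency genes at the late 8-cell stage, 16 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.19, or -1.25 at the bounds (camera adjusted p = 7.2e-07, adjusted p = 0.105 with an estimated correlation). Klf5 fell by 2.45 (SE 0.24), Zfp42 by 1.74 (SE 0.21), and Tfcp2l1 by 3.30 (SE 0.42), to 31.2 ± 8.41 from 304 ± 16.8 CPM. Nanog fell by 3.23 (SE 0.53, adjusted p = 0.000261), to 76.9 from 723 CPM. Its 4-cell and early 8-cell siRNA values straddled controls. Of 26 p53 targets 15 rose and none fell (17 adjusted over the list alone), with Btg2 at 3.21 ± 0.35, Trp53inp1 at 2.71 ± 0.31 and Mdm2 at 2.06 ± 0.36 (median 1.10, camera adjusted p = 8.1e-07, adjusted p = 0.0945 with an estimated correlation). Glycolysis genes rose, 10 of 21 against 3 that fell (10 and 4 adjusted over the list alone), with Ldhb at 4.27 ± 0.40, Eno1 at 2.37 ± 0.26 and Ldha at 2.80 ± 0.30. Pdha1 fell by 1.44 (SE 0.20), and the list's median was 1.29 (camera adjusted p = 0.000233, adjusted p = 0.132 with an estimated correlation). Of 41 maternal oocyte transcripts 14 rose and 3 fell (15 and 3 adjusted over the list alone), with Rgs2 at 5.50 ± 0.73 and the germ cell gene Dazl at 3.37 ± 0.47, and Dppa3 at -1.08 ± 0.16. Their median was 1.12 (camera adjusted p = 0.00103, adjusted p = 0.308 with an estimated correlation). Of 32 genes specific to the 2-cell stage 12 rose and 3 fell, also adjusted over the list alone, with Arg2 at 3.56 ± 0.50 and the Prame family gene Pramel6 at -1.88 ± 0.21 (median 1.98, or 2.19 at the bounds). Their camera adjusted p was 0.0439, and 0.567 with an estimated correlation, 0.0556 with DESeq2 size factors and 0.363 without siRNA replicate 1. Cumulus and granulosa cell markers rose, 6 of 13 against 0, also adjusted over the list alone, with Tnfaip6 at least 102-fold higher (8.15 ± 1.76 CPM), Cyp11a1 at least 8.96-fold higher (0.715 CPM) and Gatm at 3.39 ± 0.88. Their median was 2.99, or 3.16 at the bounds, with camera adjusted p = 0.037, and adjusted p = 0.265 with an estimated correlation, 0.0556 with DESeq2 size factors, 0.0508 without control replicate 2 and 0.0753 without siRNA replicate 2.

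The remaining lists were not called at the late 8-cell stage, although members changed. Trophectoderm genes missed narrowly (camera adjusted p = 0.0547), with 11 of 29 fallen and 4 risen, also adjusted over the list alone, Tfap2c at -2.05 ± 0.23 and the galectin gene Lgals3 at 3.48 ± 0.49. Among genes of histone crotonylation, 3 of 11 lysine acyltransferases fell (Kat2a at -1.46 ± 0.30, camera adjusted p = 0.254). Of 15 decrotonylases and deacetylases, 2 fell and 1 rose (Hdac1 at -0.81 ± 0.16, Sirt1 at 1.19 ± 0.26, camera adjusted p = 0.607). Of 21 genes of crotonyl-CoA metabolism and crotonyl-lysine readers, 8 fell and 2 rose (8 and 3 adjusted over the list alone), with the dehydrogenase gene Hadh at -1.89 ± 0.28 and the reader gene Mllt3 at 2.28 ± 0.38 (camera adjusted p = 0.096). Polarity and junction genes had 10 of 32 fallen and 3 risen (11 and 6 adjusted over the list alone), with the aquaporin gene Aqp3 at -2.87 ± 0.33 and Aqp11 at 1.92 ± 0.30 (camera adjusted p = 0.0932). Primitive endoderm genes went both ways, 3 of 20 up and 2 down (Sparc at 3.91 ± 0.57, Gata6 at -2.52 ± 0.57, camera adjusted p = 0.595). So did stress response genes, 7 of 22 up and 3 down (Hspa5 at 1.51 ± 0.22, Phgdh at -2.17 ± 0.30, camera adjusted p = 0.129). Interferon response genes had 5 of 18 risen and 1 fallen (7 and 2 adjusted over the list alone, Cxcl10 at 3.41 ± 0.76, camera adjusted p = 0.166). Cholesterol synthesis genes had 6 of 23 risen (Insig1 at 1.49 ± 0.29, camera adjusted p = 0.166). DNA methylation genes had 4 of 16 risen and 4 fallen (Tet2 at -3.18 ± 0.27, camera adjusted p = 0.75). Histone methylation genes had 4 of 32 risen and 7 fallen (Prmt5 at -1.97 ± 0.24, camera adjusted p = 0.323), and Hippo genes 1 of 20 risen and 2 fallen (Wwtr1 at -1.54 ± 0.25, camera adjusted p = 0.79). Replication-dependent histones had 5 of 44 risen, none adjusted over the list alone (Hist1h2al at 2.89 ± 0.78, camera adjusted p = 0.404). Of the markers of other cells, 2 of 5 sperm genes (Ldhc at 4.75 ± 0.57, camera adjusted p = 0.159) and 2 of 8 fibroblast genes (Fbn1 at 4.44 ± 1.48, camera adjusted p = 0.129) rose. None of 7 blood genes did (Cd74 at 1.60 ± 0.60, adjusted p = 0.0533, camera adjusted p = 0.166). Of the Y-linked genes and Xist, Eif2s3y rose by 1.02 ± 0.36 (camera adjusted p = 0.261). The number of genes called at the late 8-cell stage fell to 2296 without control replicate 1 and to 2215 without control replicate 2. Of the 75 genes named and called, 8 lost the call without 1 of the libraries, which were Msc, Nrk, Tmem59l, Ndufs1, Gatm, Hist1h2al, Fbn1 and Eif2s3y. Hist1h2al stood at 0.35 without siRNA replicate 2 (adjusted p = 0.832) and Eif2s3y at 0.57 without control replicate 1 (adjusted p = 0.359).

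**Figure D2:**
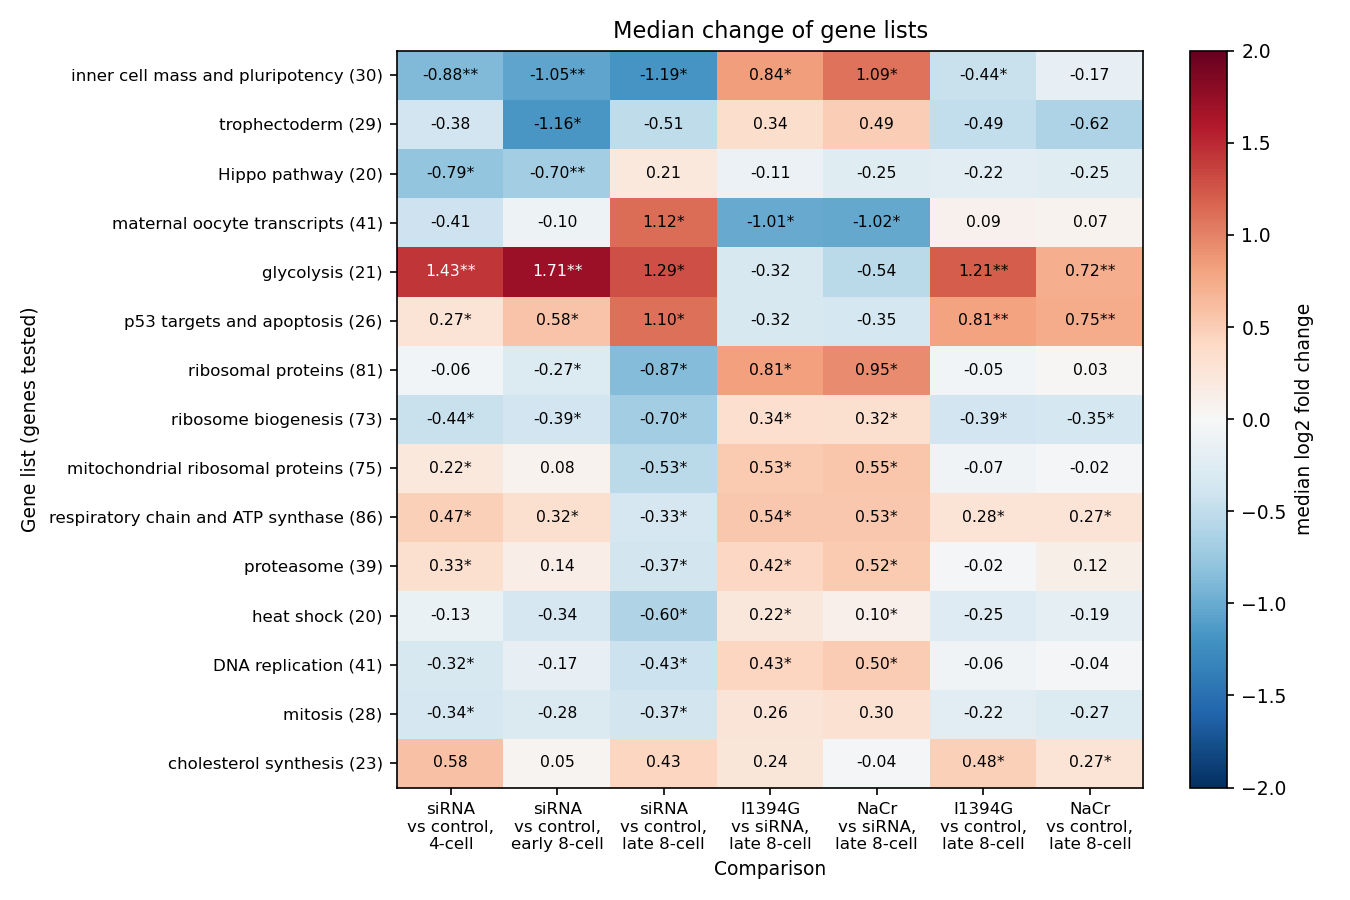
Median log2 fold change of 15 fixed gene lists (rows) in 7 comparisons (columns), printed in each cell and coloured from lower to higher. A star marks camera adjusted p under the threshold with the preset correlation and a double star also with the estimated correlation. Glycolysis genes stand at 1.43, 1.71 and 1.29 and pluripotency genes at -0.88, -1.05 and -1.19 at the 4-cell, early 8-cell and late 8-cell stages.

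Across the 3 later stages, 317 genes were higher and 488 lower at every stage, where independent lists would share 14.4 and 14.3. The 4-cell and early 8-cell comparisons shared 687 higher and 786 lower genes (106 and 99.9 for independent lists), with 2 of opposite direction. The early and late 8-cell comparisons shared 558 higher and 749 lower genes (186 and 197), with 45 and 34 of opposite direction. These comparisons share no libraries. Whether the effect of the siRNA differed between stages was tested directly, and 2703 genes differed in a joint test over the 4 stages. Of these tests, the difference between the late and early 8-cell effects passed for 1100 genes, 499 higher and 601 lower, among them Ep300 at 1.79 ± 0.52 (adjusted p = 0.0470). With DESeq2 size factors the share of higher calls in that test moved from 45.4% to 60.9%, with a shift of 0.14 in the median of all genes. The joint count was 1481 and 1641 without late 2-cell control replicates 1 and 2, 1609 and 1315 without late 2-cell siRNA replicates 1 and 2, 4394 without 4-cell control replicate 1, and 1392 and 1188 without late 8-cell control replicates 1 and 2. The count for late against early 8-cell was 575 without early 8-cell control replicate 2, 700 and 625 without early 8-cell siRNA replicates 1 and 2, 396 and 204 without late 8-cell control replicates 1 and 2, and 608 without late 8-cell siRNA replicate 1. By other fits the joint count was 4272 with DESeq2 and the late against early count 1927.

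Averaged over the 4 stages (8 libraries against 8), 5100 genes changed, 2643 higher and 2457 lower in P300 siRNA embryos. Ldha rose by 2.67 ± 0.15, from 44.4 ± 17.9 to 321 ± 165 CPM (SD over 8 libraries, adjusted p = 1.2e-08). Usp26 rose by 3.07 ± 0.18, the cyclin gene Ccnd2 by 3.40 ± 0.37 and Bex2 by 4.43 ± 0.35. Nrip3, Fam122b, Rnf128, Far1, Lmo4 and Gspt2 rose by between 1.12 and 2.51. Cnmd fell by 3.10 (SE 0.39), and Bhmt2 by 2.38 (SE 0.20). Ptpn22, Pdia5, Frmpd1, Fblim1, Mertk, Mutyh and Trim24 lay between -1.99 and -1.25. The lists of pluripotency genes (20 of 30 fell and 1 rose, 22 and 1 adjusted over the list alone, median -0.88), glycolysis (13 of 21 rose and 3 fell, 14 and 3 adjusted over the list alone, median 1.28) and p53 targets (12 of 26 rose, 14 adjusted over the list alone, median 0.49) had camera adjusted p = 8.6e-12, 1.8e-09 and 8.6e-07, and 0.0175, 0.0175 and 0.0359 with an estimated correlation. Nanog fell by 1.05 (SE 0.29, adjusted p = 0.00937). Cdx2 fell too (adjusted p = 0.00373), a call lost without some control libraries, and absent early 8-cell siRNA counts leave its size open. Klf5 stood at -1.62 ± 0.12, Eno1 at 1.997 ± 0.13 and Btg2 at 2.47 ± 0.17. Genes of crotonyl-CoA metabolism and crotonyl-lysine readers were lower as a set (10 of 21 fell and 2 rose, 11 and 3 adjusted over the list alone, Acadm at -0.61 ± 0.09 and the reader gene Cdyl2 at -1.35 ± 0.20, median -0.26, camera adjusted p = 0.023, adjusted p = 0.123 with an estimated correlation). Of the 8 other lists that passed with the preset correlation, none passed with an estimated correlation, and histone methylation missed with DESeq2 size factors (adjusted p = 0.0787).

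Whether the siRNA held embryos back was asked by following genes that change with stage in controls. In controls 10163 genes changed from late 2-cell to 4-cell, a step that may hold a batch, 187 on to early 8-cell and 4346 on to late 8-cell. Without 4-cell control replicate 1 the 187 became 928, and the 4346 became 2352 without early 8-cell control replicate 2, 2700 without late 8-cell control replicate 1 and 2010 without late 8-cell control replicate 2. DESeq2 size factors shifted the median of all genes by -0.24 between the late 2-cell and 4-cell controls, and DESeq2 called 424 genes between the 4-cell and early 8-cell controls. Gene lists were taken from controls that the siRNA comparison did not use. At the late 8-cell stage, 82 genes that fall in controls stood higher in siRNA embryos (median 0.90, 23 higher and 3 lower, camera adjusted p = 0.00038, adjusted p = 0.118 with an estimated correlation). The 101 genes that rise stood at a median of 0.12 (28 higher and 8 lower, adjusted p = 0.0301, and 0.176 with an estimated correlation). At the early 8-cell stage, 2427 rising genes stood at 0.44 and 1782 falling genes at -0.20, and at the 4-cell stage 4102 rising genes stood at -0.10 and 5446 falling genes at 0.06. None of these 6 sets passed with an estimated correlation. The rising late 8-cell set turned to -0.15 and -0.05 without 4-cell control replicates 1 and 2 and lost its call without any of 5 other libraries (adjusted p = 0.0565 to 0.35). The falling set went to 0.20 without early 8-cell control replicate 2 (adjusted p = 0.138) and to 0.14, with its call kept, without late 8-cell siRNA replicate 2 (0.0134). The 4-cell falling set lost its call without any of 5 libraries (0.055 to 0.639), and the 4-cell rising set without 4-cell control replicate 1 (0.436).

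**Figure D3:**
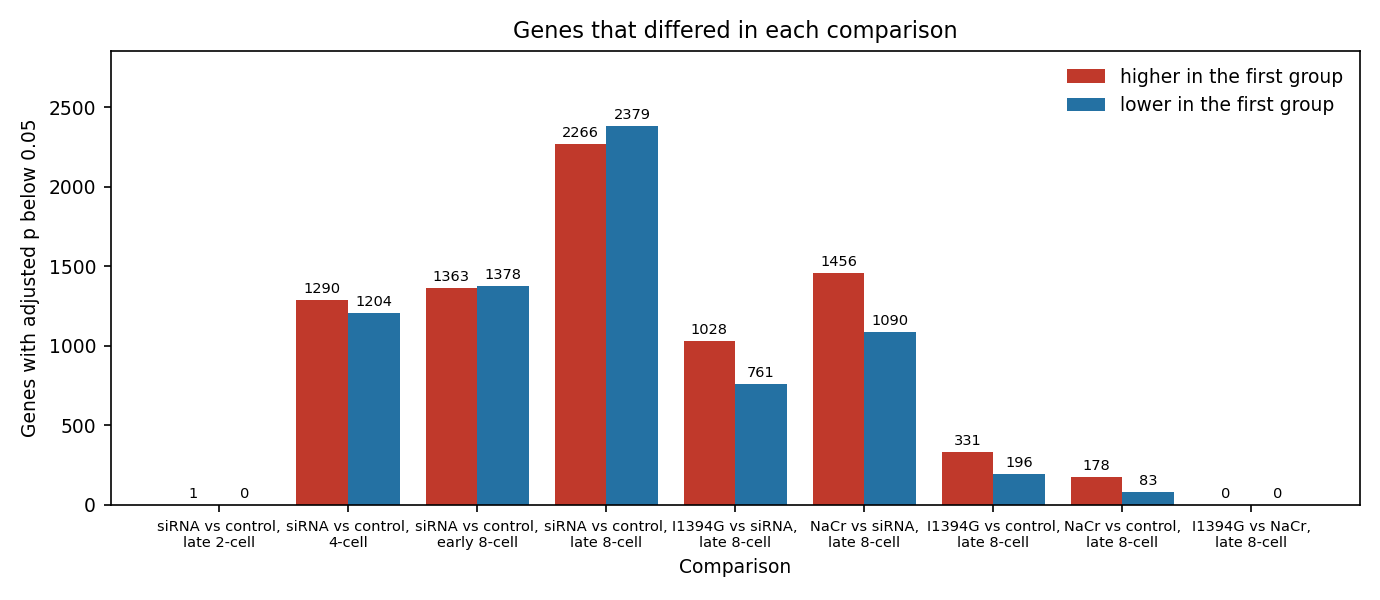
Number of genes called higher and lower (vertical axis) in each comparison, from 0. Bars are counts at an adjusted p under 0.05 in edgeR; the late 8-cell siRNA comparison holds 2266 higher and 2379 lower genes, against 331 and 196 for I1394G and 178 and 83 for NaCr compared with control.

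Between I1394G and siRNA embryos 1789 genes differed at the late 8-cell stage, 1028 higher and 761 lower with I1394G. With DESeq2 size factors the share of higher calls moved from 57.5% to 45.3%. Dppa1 rose by 4.97 ± 1.29 but by 1.10 without I1394G replicate 1 (adjusted p = 0.663), and Enpep rose by 3.43 ± 0.66 (27.3 ± 9.92 against 2.55 CPM). The sugar transporter gene Slc5a11 rose by 3.02 ± 0.41, Ly6a by 2.95 ± 0.50 and the natriuretic peptide gene Nppb by 2.91 ± 0.55. Bmyc, Rpph1, Kank4, Abo and Zfp951 rose by between 2.90 and 3.39. Rgs2 fell by 3.87 (SE 0.65), to 3.06 ± 1.09 from 44.7 ± 4.65 CPM, and Zcchc12 by 5.03. Cypt2, Dcc, Tcstv1, Zfp711, Elovl4, Gli3, Colgalt2 and Gpr50 lay between -5.78 and -3.54. Of 81 ribosomal protein genes 45 rose and none fell (73 and 1 adjusted over the list alone), with Rpl5 at 0.82 ± 0.17 (median 0.81, camera adjusted p = 6.3e-27, adjusted p = 0.334 with an estimated correlation). Of 30 pluripotency genes 14 rose and 1 fell (16 and 2 adjusted over the list alone), with Klf5 at 1.56 ± 0.23, Zfp42 at 1.11 ± 0.21 and Nanog at 2.39 ± 0.51 (median 0.84, camera adjusted p = 7.2e-07, adjusted p = 0.143 with an estimated correlation). Of 41 maternal oocyte transcripts 12 fell and 3 rose (16 and 3 adjusted over the list alone), Dazl at -2.97 ± 0.46 and Dppa3 at 1.09 ± 0.16 (median -1.01, camera adjusted p = 0.000118, adjusted p = 0.334 with an estimated correlation). Genes of ribosome biogenesis (21 of 73 rose, Ddx56 at 1.21 ± 0.15), mitochondrial ribosomes (18 of 75, Mrps2 at 1.11 ± 0.20) and the proteasome (9 of 39, Psmd3 at 1.19 ± 0.19) were higher as sets. So were those of DNA replication (9 of 41 against 1 that fell, Mcm3 at 1.35 ± 0.21), heat shock (5 of 20, Stip1 at 1.26 ± 0.16) and the respiratory chain (4 of 86, Uqcrc1 at 0.95 ± 0.20). Adjusted over the list alone, 24, 30, 14, 13, 6 and 1 of them rose and 0, 1, 1, 2, 1 and 0 fell, and none of the 6 sets passed with an estimated correlation (adjusted p = 0.143 to 0.47). Y-linked genes were lower as a set, Ddx3y at -1.54 ± 0.41, a call that did not hold with an estimated correlation (adjusted p = 0.334), without siRNA replicate 1 (0.114) or without I1394G replicate 1 (0.197). Cdx2 read 1.58 ± 0.436 CPM and its rise of 3.23 ± 1.23 did not pass (adjusted p = 0.1003). The number of genes called fell to 687 without siRNA replicate 1, to 460 without I1394G replicate 1 and to 449 without I1394G replicate 2, and the heat shock call was lost without siRNA replicate 2 (adjusted p = 0.0528). Of the 33 genes named and called, 14 lost the call without 1 of the libraries, among them Nanog without siRNA replicate 1 (adjusted p = 0.07). Without that replicate the falls of Dcc and Colgalt2 shrank to -1.36 and -2.02 (adjusted p = 0.524 and 0.349).

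Between NaCr and siRNA embryos 2546 genes differed, 1456 higher and 1090 lower with NaCr. With DESeq2 size factors the share of higher calls moved from 57.2% to 47.96%. Nanog rose by 3.37 ± 0.53, to 796 ± 36.9 from 76.9 ± 12.95 CPM (adjusted p = 0.000539), and Cdx2 by 4.68 ± 1.25, to 4.32 ± 1.36 CPM (adjusted p = 0.0178), beside 14.8 ± 1.28 CPM in controls. The Cdx2 change rests on 5 counts in siRNA replicate 2, and was 8.82 without it. Alox5ap rose by 5.17 ± 1.14 and Ly6a by 3.59 ± 0.52. Siglecg, Slc5a11, Pik3r6, Bmyc, Rab17, Nppb and Tat lay between 3.04 and 4.37. The orphan receptor gene Gpr50 fell by 5.24 (SE 0.68), Rgs2 by 4.38 (SE 0.69), and Cypt2 to a single count (0.0622 against 11.2 CPM). Tcstv1, Pwwp3b, Zfp711, Calb1 and Amer1 lay between -4.65 and -4.02. Of 81 ribosomal protein genes 58 rose and 1 fell (76 and 1 adjusted over the list alone), Rpl5 at 1.19 ± 0.17 (median 0.95, camera adjusted p = 8.0e-29, adjusted p = 0.355 with an estimated correlation). Of 30 pluripotency genes 16 rose and 1 fell (18 and 2 adjusted over the list alone), Zfp42 at 1.37 ± 0.21 (median 1.09, camera adjusted p = 1.3e-07, adjusted p = 0.0814 with an estimated correlation). Genes of ribosome biogenesis (27 of 73 rose, Ddx56 at 1.23), mitochondrial ribosomes (25 of 75 against 1 that fell, Mrpl17 at 1.24 ± 0.22) and the proteasome (13 of 39, Psmd8 at 1.06 ± 0.17) were higher as sets. So were those of DNA replication (16 of 41, Mcm3 at 1.48 ± 0.21), heat shock (6 of 20 against 1 that fell, Stip1 at 1.498 ± 0.17) and the respiratory chain (11 of 86, Uqcrc1 at 0.98 ± 0.20). Adjusted over the list alone, 29, 39, 21, 18, 6 and 10 of them rose and 0, 1, 0, 1, 1 and 0 fell, and none of the 6 sets passed with an estimated correlation (adjusted p = 0.0814 to 0.484). Of 41 maternal oocyte transcripts 12 fell and 3 rose (15 and 3 adjusted over the list alone), with Kit at -2.90 ± 0.47 and Dppa3 at 1.39 ± 0.16 (adjusted p = 0.482 with an estimated correlation). The number of genes called fell to 1455 without siRNA replicate 1, to 1311 without NaCr replicate 1 and to 912 without NaCr replicate 2. Without siRNA replicate 2 the calls of maternal transcripts and of heat shock genes were lost (adjusted p = 0.0518 for both). Of the 29 genes named and called, 10 lost the call without 1 of the libraries. The Cdx2 call was lost without siRNA replicate 1, siRNA replicate 2 or NaCr replicate 1 (adjusted p = 0.086, 0.083 and 0.0763).

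**Figure D4:**
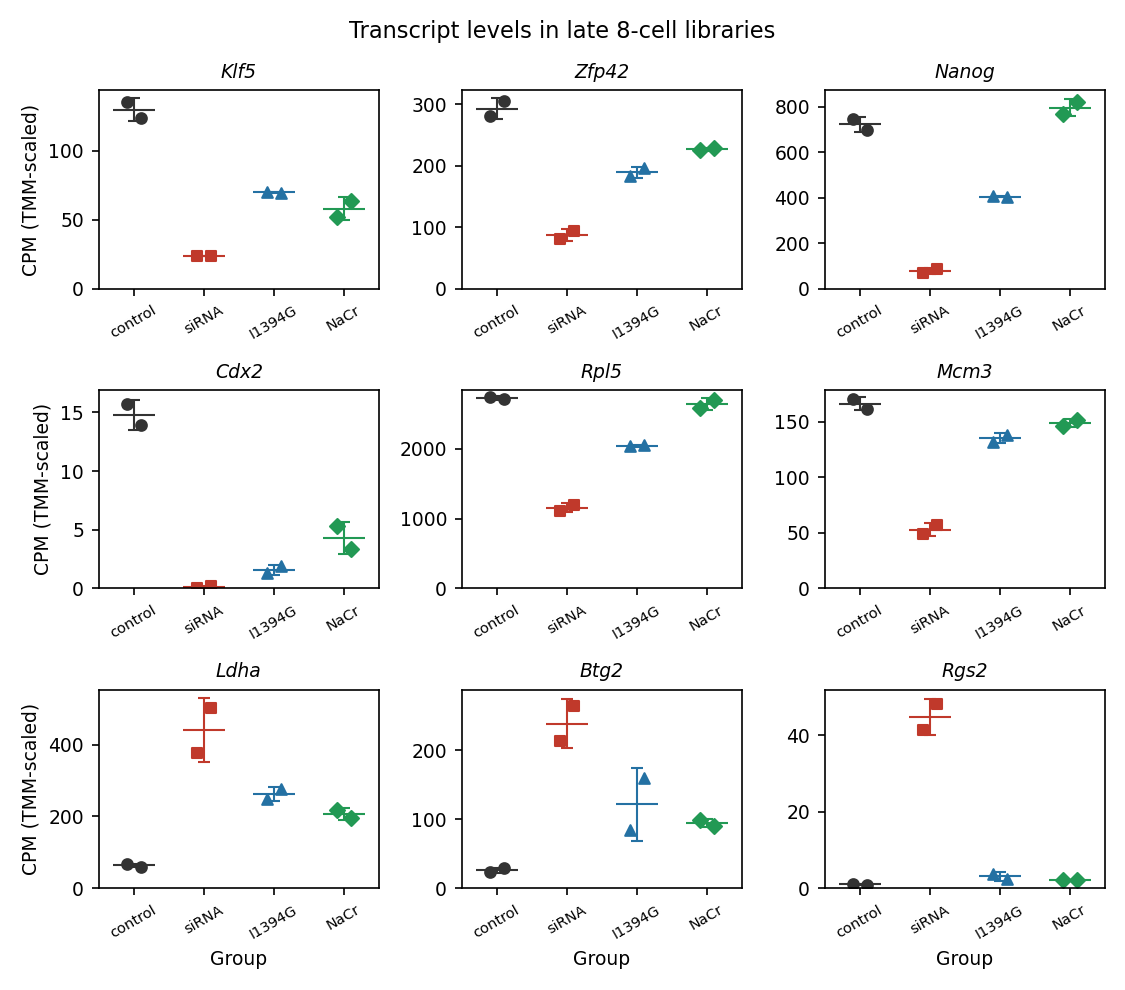
Level in CPM (vertical axis, from 0 in each panel) of 9 genes in the 4 late 8-cell groups. Points are libraries, horizontal lines are means and bars show the SD (n = 2); Nanog read 723 ± 33.7 in controls, 76.9 ± 12.95 with siRNA, 404 ± 2.31 with I1394G and 796 ± 36.9 with NaCr.

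How far both treatments undid the siRNA changes was measured on genes chosen in other embryos, the early 8-cell calls, which share no library with the late 8-cell groups. The 1378 genes lower at the early 8-cell stage had a median of 0.61 in I1394G against siRNA embryos, 79.5% of them above 0 (camera adjusted p = 2.5e-25, and 0.00206 with an estimated correlation). In NaCr against siRNA embryos it was 0.70, 79.0% above 0 (1.6e-28, and 0.00206 with an estimated correlation). The 1363 higher genes had medians of -0.49 with I1394G, 73.7% below 0 (2.4e-08, and 0.0319 with an estimated correlation), and -0.64 with NaCr, 75.9% below 0 (5.0e-10, and 0.0235 with an estimated correlation). Of the lower genes 412 rose again with I1394G and 533 with NaCr, and of the higher genes 169 and 266 fell. In siRNA against control embryos at the late 8-cell stage, these 2 sets had medians of -0.95 and 0.95, and in the treated groups against control -0.34 and 0.42 with I1394G and -0.25 and 0.28 with NaCr. Of the genes called at the late 8-cell stage itself, I1394G moved 575 of 2266 higher genes (25.4%) and 929 of 2379 lower genes back, and NaCr 816 (36.0%) and 1244 (52.3%). Independent lists would share 104, 147, 149 and 209. This count shares the siRNA libraries between both comparisons, and the correlation across genes was -0.735 for I1394G and -0.747 for NaCr, where simulated groups equal to the siRNA embryos gave -0.215 and -0.205 and at most 1 gene called back. With no effect of the siRNA simulated either, the shared libraries alone gave correlations of -0.565 and -0.532 and 0 genes called back. The covariance was -1.85 and -2.16, against -0.360 and -0.364 in the first of these simulations and -0.364 and -0.363 in the other. Of the lower genes 159 (I1394G) and 66 (NaCr) still differed from control, and of the higher 287 and 151. Medians against control were -0.43 and -0.32 (lower) and 1.26 and 0.89 (higher). Uncalled genes need not have returned. The 1504 and 2060 called back were fewer without control replicate 2, siRNA replicate 1 or either treated replicate.

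**Figure D5:**
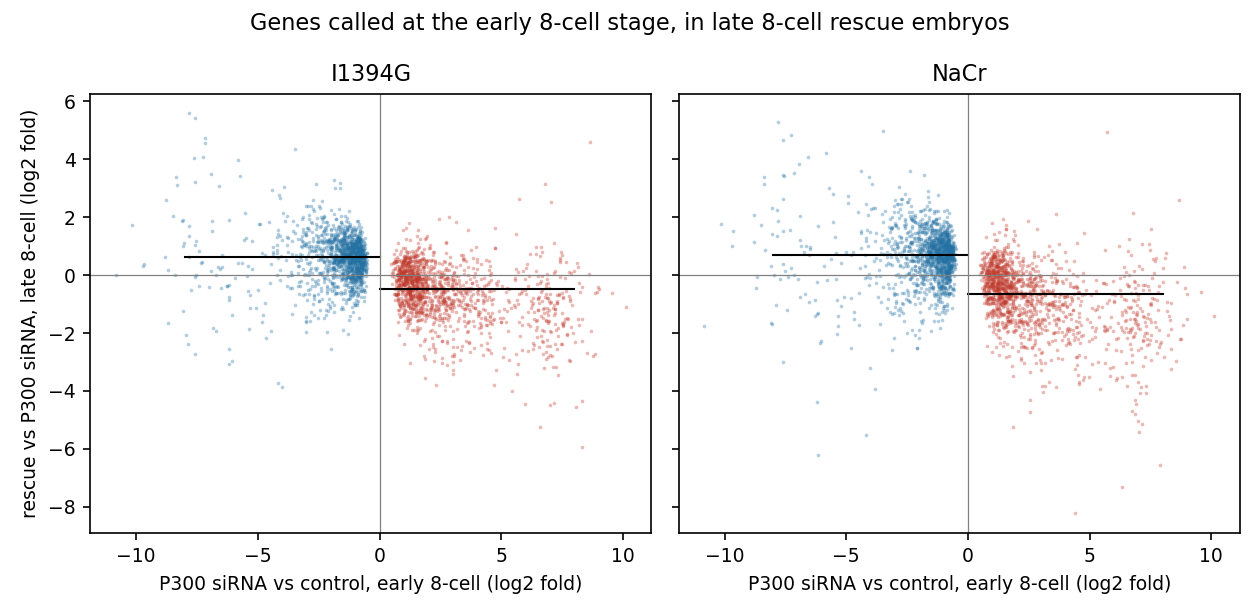
Each point is 1 of the 2741 genes called at the early 8-cell stage, with its log2 fold change there (horizontal axis) and its late 8-cell log2 fold change in I1394G or NaCr against siRNA embryos (vertical axis). Black lines mark medians, which stand at 0.61 and -0.49 with I1394G and at 0.70 and -0.64 with NaCr.

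Against control embryos, 527 genes differed with I1394G, 331 higher and 196 lower. Sncg was at least 300.1-fold higher, the secreted peroxidase gene Gpx3 rose by 5.74 ± 0.61, the tetraspanin gene Cd81 by 4.56 ± 0.54 (66.8 ± 16.6 against 2.83 CPM) and Igfbp6 by 4.73 ± 0.60. Trh, Taf7l, Rhox6 and Rhox2a rose by between 4.27 and 5.56, and Mzb1 (17.1 CPM) and the metallothionein gene Mt3 (10.1 against 0.0552 CPM) rose from 3 and 2 control counts. Smpdl3a, a phosphodiesterase gene, fell by 2.97 (SE 0.57), to 22.8 ± 1.23 from 179 ± 19.3 CPM, Ly6f by 4.27 (SE 0.85), Otx2 by 3.08 (SE 0.83) and the planar polarity gene Vangl1 by 2.66 (SE 0.44). Fmnl2, Cnmd, Tex14, Bambi, Prl3b1 and Lypd8 lay between -3.18 and -2.31. Glycolysis genes stayed higher, 9 of 21 against 0 (12 and 1 adjusted over the list alone), with Pkm at 1.89 ± 0.24 and Ldha at 2.05 ± 0.29 (median 1.21, camera adjusted p = 3.3e-11, and 0.00849 with an estimated correlation). So did p53 targets, 8 of 26 against 0 (12 adjusted over the list alone), with Btg2 at 2.24 ± 0.34 (median 0.81, camera adjusted p = 7.7e-11, and 0.00849 with an estimated correlation). Cholesterol synthesis genes (5 of 23 rose, 7 adjusted over the list alone, Sqle at 1.33 ± 0.24, adjusted p = 0.433 with an estimated correlation) and cumulus and granulosa markers (2 of 13 rose, 3 adjusted over the list alone, Cyp11a1 at least 40.6-fold higher, adjusted p = 0.113 with an estimated correlation) were higher as sets. Genes specific to the 2-cell stage (1 of 32 rose, Klf17 at 2.52 ± 0.48, with 6 up and 1 down adjusted over the list alone, adjusted p = 0.61 with an estimated correlation) and respiratory chain genes (1 of 86 rose, Cox6b2 at 3.34, adjusted p = 0.645 with an estimated correlation) were higher as well. The respiratory chain call was lost without control replicate 1 (0.0688). Ribosome biogenesis genes (4 of 73 fell, 12 adjusted over the list alone, Wdr12 at -1.23 ± 0.21, adjusted p = 0.433 with an estimated correlation) and pluripotency genes (3 of 30 fell, 4 down and 1 up adjusted over the list alone, Etv5 at -1.85 ± 0.38, adjusted p = 0.481 with an estimated correlation) were lower. The pluripotency call was lost without control replicate 1 (0.087) and without I1394G replicate 2 (0.135). Cdx2 (-3.21 ± 0.99, adjusted p = 0.0921) and Nanog (-0.84 ± 0.48, adjusted p = 0.402) did not pass. The count of 527 became 56 and 63 without control replicates 1 and 2, 98 and 162 without I1394G replicates 1 and 2, 1057 with DESeq2 and 4031 with only these 4 libraries. Of the 29 genes named and called, 21 lost the call without 1 of the libraries, among them Btg2 without control replicate 1 (adjusted p = 0.0529).

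With NaCr, 261 genes differed from control embryos, 178 higher and 83 lower. Hmox1, the heme oxygenase that oxidative stress induces, rose by 3.60 ± 0.39, to 365 ± 23.3 from 30.2 ± 0.479 CPM (adjusted p = 0.000217), Gpx3 by 5.15 ± 0.60 and Cd81 by 4.03 ± 0.53, and Sncg was at least 180.5-fold higher. Mzb1 and Mt3 rose from few control counts, and Taf7l, Igfbp6, Klhl13 and the galectin gene Lgals1 rose by between 3.60 and 4.96. Gsto1, a glutathione transferase gene, fell by 2.12 (SE 0.42), to 151 ± 40.4 from 656 ± 109 CPM, with Cnmd, Trpc5os, Dynap, Smpdl3a, Vangl1, Cct6b, Tspan8, Tex14 and Tspan1 between -3.77 and -2.12. Glycolysis genes stayed higher, 6 of 21 against 0 (9 and 1 adjusted over the list alone), with Eno1 at 1.82 ± 0.25 and Ldha at 1.71 ± 0.29 (median 0.72, camera adjusted p = 2.6e-10, and 0.00919 with an estimated correlation). So did p53 targets, 7 of 26 against 0 (11 adjusted over the list alone), with Btg2 at 1.88 ± 0.33 (median 0.75, camera adjusted p = 2.0e-10, and 0.00919 with an estimated correlation). The sets of cholesterol synthesis (3 of 23 rose, 5 adjusted over the list alone, Fdps at 1.999 ± 0.33), 2-cell genes (1 of 32 rose and 1 fell, 13 and 1 adjusted over the list alone, Klf17 at 1.93 and Fgf1 at -1.42), the respiratory chain (1 of 86 rose, Cox6b2 at 2.60) and cumulus and granulosa markers (2 of 13 rose, Cyp11a1 at least 37.4-fold higher) were higher. Ribosome biogenesis genes were lower (2 of 73 fell, also adjusted over the list alone, Wdr12 at -0.97), and none of these 5 sets held with an estimated correlation (adjusted p = 0.6, 0.602, 0.602, 0.146 and 0.6). Without NaCr replicate 2 the 2-cell median turned to -0.04. Cdx2 (-1.77 ± 0.94, adjusted p = 0.440) and Nanog (0.14 ± 0.48, adjusted p = 0.965) did not pass. The count of 261 became 12 and 36 without control replicates 1 and 2, 113 and 66 without NaCr replicates 1 and 2, 728 with DESeq2 and 2263 with only these 4 libraries. Of the 29 genes named and called, 26 lost the call without 1 of the libraries. Without control replicate 2 the calls of Ldha, Btg2 and Gsto1 were lost (adjusted p = 0.115, 0.0803 and 0.136).

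Between I1394G and NaCr embryos edgeR and DESeq2 called no gene, and edgeR held 323 (fewer than by chance) at an unadjusted p under 0.05. A fit without the filter on low counts called 20 genes, a fit of these 4 libraries 2, and edgeR without NaCr replicate 2 called 1. Nanog stood at -0.98 ± 0.48, Cdx2 at -1.45 ± 0.95 and Rpl5 at -0.37 ± 0.17 (all adjusted p = 1). Ribosomal protein, ribosome biogenesis, proteasome and Y-linked genes were lower as sets with I1394G, without a member that passed (Rpl41 at -0.06 ± 0.25, Npm1 at -0.14 ± 0.15 and Psmb6 at -0.05 ± 0.21 as the most abundant members). Their camera adjusted p values were 0.00293, 0.0491, 0.00239 and 0.00239, against 0.929, 0.929, 0.929 and 0.365 with an estimated correlation. Without NaCr replicate 2 the calls of ribosomal protein and ribosome biogenesis genes were lost (0.456 for both), without NaCr replicate 1 the proteasome call (0.182), and without I1394G replicate 1 the Y-linked call (0.27). The ribosome biogenesis call was also lost without I1394G replicate 1 (0.187) or 2 (0.0691).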

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

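All tests of explanations in these paragraphs were chosen after the results they weigh were seen, except the test for background reads over silent genes.

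The effect of the siRNA differed between stages for 2703 genes in the joint test and between the late and early 8-cell stages for 1100 genes, among them Ep300, whose change was 1.79 on the log2 scale less negative at the late stage. The FPKM and count columns of control early 8-cell replicate 2, a comparison outside the main measurement, correlated at 0.899, where the other libraries reached at least 0.997.

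Many genes differed at the late 8-cell stage (4645) although Ep300 did not, which could point to an artefact of the late libraries. Low depth of siRNA replicate 1 was argued against, since 3307 genes were called without it, 3020 of them called with all libraries and in the same direction, and 3425 without replicate 2. Libraries from outside the siRNA arm under its label were argued against too, since 90.3% of the 786 genes lower at both earlier stages were lower here (median -1.02), as were 81.7% of the 687 higher genes higher (median 0.99). Higher calls rose by a median of 7.80 CPM, and 99.03% by over 0.410 CPM, the 99th percentile of 1491 silent receptor genes. The low-count filter and the call favour such rises, so background reads stay open. Ep300 fell in controls, by -1.74 (log2) from early to late 8-cell, so a knockdown may no longer show here while its effects do. This stays open, as does a timing difference between the arms, since no stage-changing set passed with an estimated correlation.

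The unmatched FPKM column may hold values of a library of the siRNA arm. Over the 602 genes lower in siRNA embryos at the 4-cell and late 8-cell stages its median difference from control replicate 1 was -0.81, against -0.77 and -0.80 in the FPKM of siRNA replicates 1 and 2. Over the 449 higher genes it was 0.75, against 1.27 and 1.12. The count column of the same library gave 0.068 and -0.17, which argues against an exchange in the counts, and the 19 other libraries matched, which argues against a step common to all columns. Which library the FPKM values came from stays open.

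After the late 2-cell stage, 286 genes were higher and 257 lower in each of 10 siRNA-arm libraries than in each of 6 controls. With exchangeable libraries 2.07 of each would arise (0.0125%). X-linked genes made up 15.7% of the higher (45), 1.17% of the lower (3) and 4.12% of tested genes. For independent genes two-sided Fisher's exact p was 7.5e-15 and 0.0106. A female surplus could give this. At the late 8-cell stage that was argued against for embryos with P300 siRNA alone. Their summed Y-linked CPM was higher than that of controls by 1.17 on the log2 scale (400 ± 68.5 against 177 ± 72.5 CPM). At the early 8-cell stage it was not lower either (0.17, 159 ± 31.1 against 142 ± 13.9 CPM), although 118 X-linked genes rose there. At the 4-cell stage it was lower (-0.72, 131 ± 36.1 against 217 ± 44.9 CPM), and sex balance and siRNA cannot be told apart there with 2 libraries per group. Mice of another strain in the siRNA arm would show at the late 2-cell stage, where the 111 abundant higher genes stood at a median of -0.030 against 1.77 later, but embryos of the stages need not share parents, so strain cannot be told apart either. An effect of the siRNA, which the design names, stays open beside them.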

How the results depend on the processing

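The fit without the late 2-cell libraries and the FPKM fit without the unmatched column were chosen only after the data were seen, and all other alternatives before. Counts below are genes called, with the count by edgeR on all libraries in brackets, and for every shift the cause was not tested except where the text states it. DESeq2 size factors kept every count within 1.5 times and every set call among the 28 results on comparisons and sets. They turned the majority direction of calls at the late 8-cell stage, in late against early 8-cell and in I1394G and NaCr against siRNA (shares of higher calls of 58.4%, 60.9%, 45.3% and 47.96%). They kept 83 of the 87 calls of gene lists and 300 of the 301 calls of named genes, and lost only that of Otx2 with I1394G against control (adjusted p = 0.0537). The DESeq2 Wald test kept 9 results and gave 33 genes at the late 2-cell stage (1), 1057 in I1394G against control (527), 728 in NaCr against control (261), 4272 in the joint test of stages (2703), 1927 in late against early 8-cell (1100) and 424 between early 8-cell and 4-cell controls (187). Without a filter on low counts 6 results were kept, and the same comparisons gave 12, 1140, 793, 4473 and 1885 genes from the late 2-cell stage to late against early 8-cell, with 20 between I1394G and NaCr (0). With limma on FPKM the late 2-cell, 4-cell and early 8-cell comparisons gave 79, 1368 (2494) and 165 (2741) genes, I1394G against control 330 and NaCr against control 147, and 5 comparisons were kept. Without the unmatched FPKM column the early 8-cell comparison gave 1661. With only the libraries of the groups compared, which leaves 2 residual degrees of freedom, the late 2-cell comparison gave 508 genes, the 4-cell 59, I1394G and NaCr against control 4031 and 2263, and I1394G against NaCr 2, with 5 comparisons kept. Without the late 2-cell libraries I1394G and NaCr against control gave 337 and 160 genes and late against early 8-cell 638, and 8 comparisons were kept. A minimum log2 fold change of 1 left 2308 of 5100 genes in the average over stages by its construction and kept 9 comparisons.

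With the correlation estimated for each list, 12 of 87 list calls held. None of the sets of stage-changing genes did, at late 8-cell medians of 0.12 (rising, adjusted p = 0.176) and 0.90 (falling, 0.118), early 8-cell medians of 0.435 and -0.20, and 4-cell medians of -0.10 and 0.060 (0.176 for each of these 4). All 4 early 8-cell sets followed into the treated groups held. Samples sharing a replicate number did not deviate together, with correlations of the deviations in same-stage groups of 0.05, 0.14 and 0.01 at the first 3 stages and at most 0.03 at the late 8-cell stage. As a hint from the data and not the design, the 4-cell and early 8-cell siRNA libraries correlated at 0.42. A replicate block kept 23 results and gave 0 genes at the late 2-cell stage and 86 between early 8-cell and 4-cell controls, with medians of 0.15 (rising, late 8-cell, adjusted p = 0.0882), 0.14 (falling, late 8-cell, 0.305) and 0.12 (falling, 4-cell, 0.0651). It kept 83 list calls and 298 calls of named genes.

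Without each library in turn, a group may hold 1 library, which is assumed to vary like the other groups. The siRNA comparisons then gave 0 to 1 (late 2-cell), 1383 to 3107 (4-cell), 1313 to 2365 (early 8-cell), 2215 to 3425 (late 8-cell) and 4167 to 5539 genes (average). I1394G and NaCr gave 449 to 1948 and 912 to 2282 against siRNA, 56 to 162 and 12 to 113 against control, and 0 to 1 against each other. The joint test gave 1188 to 4394 and late against early 8-cell 204 to 1404, and successive control stages 8349 to 9304, 113 to 928 and 2010 to 3642. Genes called back numbered 419 to 1594 with I1394G and 852 to 1863 with NaCr. Medians of the early 8-cell sets ran from 0.55 to 0.72 and -0.57 to -0.28 with I1394G and from 0.65 to 0.85 and -0.73 to -0.42 with NaCr, and were called each time. Medians of stage-changing sets ran from -0.15 to 0.22 (rising) and 0.14 to 1.02 (falling) at the late 8-cell stage, from 0.20 to 0.63 and -0.32 to -0.12 at the early 8-cell stage, and from -0.16 to 0 and 0 to 0.31 at the 4-cell stage. The rising late 8-cell set reversed without 4-cell control replicate 1 (-0.15, adjusted p = 0.036) and without replicate 2 (-0.05, 0.421). Between 81 and 92 list calls passed. Of those tested this way 451 were the same, 39 were lost and 2 reversed, the late 8-cell respiratory chain without siRNA replicate 1 (0.063, range from there to -0.87) and 2-cell genes in NaCr against control without NaCr replicate 2 (-0.036, range from there to 2.62). For named genes 1304 calls were the same, 224 were lost and none reversed, and in the average over stages only that of Cdx2 was lost. The DESeq2 Wald test lost the call of 1 named gene, Msc at the late 8-cell stage, and limma on FPKM lost 81 of 300, of which 36 lay in the early 8-cell comparison with the unmatched column.

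With few genes changed (62 to 70 calls), 12% to 20% of simulated 2-fold changes were found. This need not hold at later stages (2494 to 4645 calls). What limits it was not tested. Late 8-cell siRNA replicate 1 held the fewest counts (3.20 M), and what this costs for genes of low level was not tested.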

Other observations

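The tests of X-linked and imprinted genes were chosen after rises of single members were seen, and the test of other splits of the labels before.

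The share of X-linked genes called higher in P300 siRNA embryos was above that of other genes, a difference in shares that was not itself tested. Of 684 tested, 147 rose and 15 fell at the 4-cell stage (21.5% against 7.17% of other genes that rose), 118 rose and 26 fell at the early 8-cell stage (17.25% against 7.79%), and 173 rose and 41 fell at the late 8-cell stage (25.3% against 13.05%). In NaCr against siRNA embryos 29 rose and 87 fell (4.24% and 12.7%, against 8.98% and 6.25% of other genes), and in I1394G against siRNA embryos 26 rose and 44 fell (3.80% and 6.43%, against 6.32% and 4.46%). Whether X-linked genes rise together, as delayed silencing of an X chromosome could make them, was tested as a set, and with an estimated correlation the list did not pass at the 4-cell, early 8-cell or late 8-cell stage (camera adjusted p = 0.180, 0.3445 and 0.317 over the 30 tests of these lists, against 2.3e-08, 0.000393 and 9.6e-05 at the preset correlation), or in I1394G or NaCr against siRNA embryos (0.7045 and 0.3445).

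Imprinted genes, which are expressed from the allele of a single parent, rose as a group at the late 8-cell stage. Of 35 tested, 17 rose and 1 fell, with a median log2 fold change of 2.22, and the list passed with an estimated correlation (camera adjusted p = 0.0439). In a permutation test over genes, none of 10000 random lists of the same size and mean expression had so high a median (permutation p = 0.0001, the smallest these draws can give). The same permutation test over genes gave p = 0.0047 at the early 8-cell stage and p = 0.112 at the 4-cell stage. It takes no account of correlation between genes, and at neither of these stages did the list pass camera with the preset correlation (adjusted p = 0.0569 and 0.0780) or with an estimated correlation (0.317 for both). Among the largest changes were those of the cell cycle inhibitor gene Cdkn1c at 5.11 and the placental gene Phlda2 at 4.70. Both stood above control with I1394G (3.73 and 3.88) and with NaCr (3.07 and 3.53). Against control the list passed in both treated groups (camera adjusted p = 0.0439 for each with an estimated correlation, with 3 and 4 members called), and against siRNA it was lower at the preset correlation only (0.104 and 0.111 with an estimated one). Impact, of translation control, was higher by 1.88, 1.61 and 1.99 at the 3 later stages, and Zdbf2 by 1.79, 1.83 and 2.53. These examples were chosen after their values were seen. A loss of imprinted silencing may be 1 reading, and release of many silent genes another, since the siRNA libraries also detected more genes at equal depth there, as they did at the 4-cell stage (14340 ± 67.9 against 13707 ± 82.0) and the early 8-cell stage (14552 ± 216 against 13708 ± 373), where the list did not pass. Cumulus and granulosa cell markers rose in the same comparison (6 of 13, median 2.99, or 1.89 without siRNA replicate 2), a call lost with an estimated correlation (adjusted p = 0.265) and with DESeq2 size factors (0.0556). Whether somatic cells carry part of the imprinted rise was not tested. A narrower hypothesis, that genes imprinted through maternal H3K27me3 rise together, stays open, since the 25 such genes passed at 0 of the 3 later stages. Their medians were 0.44, -0.69 and -0.34, with 3, 2 and 4 risen and 2, 3 and 2 fallen. Sfmbt2, a member, was higher by 3.97, 3.86 and 1.55. Reads from each parental allele were not analysed here.

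Chance as the source of the 5100 genes called in the average over stages was tested by exchanging labels within stages. Of 648 possible splits 100 were drawn, and 1, the real one, gave as many genes. The highest other gave 1827, so chance was unlikely but not excluded.

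The late 2-cell libraries stood apart from the rest, with between 116 and 139 of the silent receptor genes showing a count at equal depth, against 28 to 71 in the other libraries. They detected 16678 to 16959 genes at that depth, against 13444 to 16777 elsewhere. A batch of their own cannot be told from stage in the step to 4-cell controls or 4-cell stage-changing genes. The joint test uses their siRNA effects.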
